A study of Homo sapiens with 12 samples.

How the data were processed

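Gene-level counts of 12 RNA sequencing libraries from transfected HEK293T cells were analysed, 3 for each of 4 gRNA groups. Poly(A) RNA was selected with oligo(dT) beads, fragmented and made into libraries, per the labels' protocols. The raw counts per gene were deposited by the authors, 1 table per library, with a gene length beside each count. Reads were demultiplexed with bcl2fastq 2.17.1.14, trimmed with Trim Galore 0.6.7 and aligned with STAR 2.7.9a to GRCh38, per the submitters' processing notes. The counting tool, the annotation, the use of strand and the handling of reads that map to several places are not given in the sources used here. This matters for HBG1 and HBG2, for pseudogenes and for antisense genes, whose counts may miss reads or hold reads of a partner. All 37 mitochondrially encoded genes had 0 counts in all libraries. Comparison with public HBG expression, which the design text mentions, was not analysed here.

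Each table held 60424 entries. The later entry of 6 repeated identifiers was left out, which gave 60418 genes. Groups and replicate numbers were taken from the labels. Replicates of each group were compared by a chi-square test of their counts over genes with at least 20 counts; the chi-square per degree of freedom lay between 1.36 and 5.37, so no pair agreed within sampling noise. Total counts per library ranged from 11378120 to 13059030, at which 3 counts in a library correspond to 0.231 to 0.265 CPM, counts scaled to the library size. Coordinates and exons are those of GENCODE 29 on GRCh38, in which 58173 identifiers were found; the gene lengths in the tables of HBG1 and HBG2, 1467 and 841 bases, differ from the exon unions of GENCODE 29, 1659 and 869.

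Genes were tested with edgeR 4.0.16 in R 4.3.3, by the quasi-likelihood F test with robust dispersions, on all 12 libraries in 1 fit with a mean per group. The fit kept 16285 genes by filterByExpr and used TMM scaling factors, which lay between 0.986 and 1.01. The biological coefficient of variation was 4.11%. P-values were two-sided and adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. The SE of a log2 fold change was taken as its size divided by the square root of F. The 6 comparisons between groups, the mean of the 3 HBG-targeting groups against NC and a test among all 4 groups were made. CPM are counts divided by the TMM-scaled library size, given as mean ± SD of 3 libraries. HBG1 and HBG2 were also summed to 1 gene and tested in the same way, with exact permutation tests of log2(CPM + 0.1) and exact 95% intervals for ratios of count rates. Where NC had 0 counts, a bound was computed as the observed mean of the other group over a floor of 3 counts across the NC group. Folds given as at least a value are such bounds, and they cover the counting error of NC but not that of the other group. With 1 to 10 counts in NC, ratios have exact binomial intervals, which cover counting error only.

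A total of 25 gene lists were fixed before the data were examined, of which 21 had at least 3 tested genes. They were tested with camera (limma 3.58.1) on voom values with a preset correlation of 0.01 and, as alternatives, an estimated correlation and fry.

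Genes named in the text follow a rule fixed before the data were examined. It names HBG1, HBG2, the other globin cluster genes, RELA and genes within 100 kb of HBG1 or HBG2. In each comparison it names up to 10 rises and 10 falls, the largest among genes with a symbol, an adjusted p under 0.05, a mean of at least 1 CPM and no overlap between the 2 groups. It names up to 4 called members of each list, or 2 of the highest level as values where none was called. Where fewer than 5 genes qualify in a comparison, it names the 5 with the smallest p, and for the mean contrast it names 5 rises and 5 falls. Genes named outside the rule are said to be so.

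The alternatives fixed before the data were examined were RLE and upper-quartile factors, DESeq2 1.42.0, limma-voom, no low-count filter, a filter of 1 CPM in 3 libraries, a fit of the 2 compared groups alone, the replicate number as a block, a log2 fold change of at least 1, HBG1 alone, and leaving out each library in turn. Alternatives added after the data were seen were the interferon list without PARP14, and offsets per library for smooth trends with GC content of the longest GENCODE 29 transcript and gene length. A GC value was found for 16100 of the 16285 genes, and 1 specification of the offsets was run.

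The pipelines were tested on simulated counts drawn from the means, library sizes and dispersions of these libraries, with 50 genes changed at each fold in circular against NC and 16078 genes tested. The changed genes were drawn among those with a mean of at least 1 CPM, and the counts held no GC or length trends. Recovery at lower levels and false calls under such trends were therefore not measured. edgeR recovered 52% of the genes changed 1.25-fold, 78% at 1.5-fold, 92% at 2-fold and 100% at 4-fold; 10 calls, 5.85%, were false. In the unchanged comparisons of the simulation it called 0 genes in linear against NC, 1 in U6 against NC and 0 in linear against U6. With the GC and length offsets 52%, 80%, 92% and 100% were recovered. A simulated 1.2-fold rise of the p53 list in circular against NC gave a camera adjusted p of 6.1e-15, and 0 of the other lists passed. Genes were drawn independently of one another there, so it could not show the false list calls that correlated genes bring. Shared controls were simulated 20 times with unchanged groups.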

Results

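RNA sequencing was used to measure the transcriptome of transfected HEK293T cells, a human embryonic kidney line. The series design text describes the cells as a knock-in cell line carrying doxycycline-inducible dCas12f-VPR, a small catalytically dead Cas12f nuclease fused to the VPR transcriptional activator. The genotype field of the labels calls the same cells wild type, and the cell line field and titles number the line differently in each group. Each well received 32 ng of a plasmid encoding a guide RNA (gRNA) and 968 ng of the pBluSKM vector plasmid, and RNA was collected 3 days after transfection. Which groups received doxycycline is not given in the sources used here, so a difference from NC is read on the assumption that all groups were treated alike in this. There were 4 groups of 3 libraries each. In 3 groups the gRNA targeted HBG, the fetal gamma-globin genes, and was encoded in a U6, a linear or a circular form. In the control group, called NC, the gRNA targeted mNeonGreen, a fluorescent protein gene foreign to the human genome. The same NC group served all 3 forms, and its description does not name a form of gRNA. In comparisons with NC, the form of the gRNA may therefore differ together with its target. Total gene counts per library lay between 11378120 in circular replicate 1 and 13059030 in NC replicate 3. Nothing in the labels says that the replicates were separate cultures, so p-values measure the spread between these libraries, which may be technical.

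The question behind the design was whether a circular gRNA raises dCas12f-based activation of HBG. HBG1 (ENSG00000213934) lies on chromosome 11 at 5248079 to 5249859 of GRCh38, on the minus strand, and HBG2 (ENSG00000196565) is its near-identical neighbour. HBG1 was counted 130, 105 and 107 times in circular replicates 1, 2 and 3. The counts were 4, 9 and 7 in the linear group and 5, 5 and 3 in the U6 group. All 3 NC libraries had 0 counts of HBG1. HBG2 received 1 count in linear replicate 2, 1 count in circular replicate 3 and 0 in the other libraries. Because reads of the copies may be split or dropped by the counting, the sum of HBG1 and HBG2 is the main value. It was 9.63 ± 1.65 CPM (counts scaled to the library size; SD, n = 3) with the circular gRNA, 0.556 ± 0.231 with the linear gRNA and 0.351 ± 0.0806 with the U6 gRNA. Over the NC group as a whole, 0 counts allow a level of up to 0.0828 CPM. This floor and the intervals below cover counting error only.

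**Figure D1:**
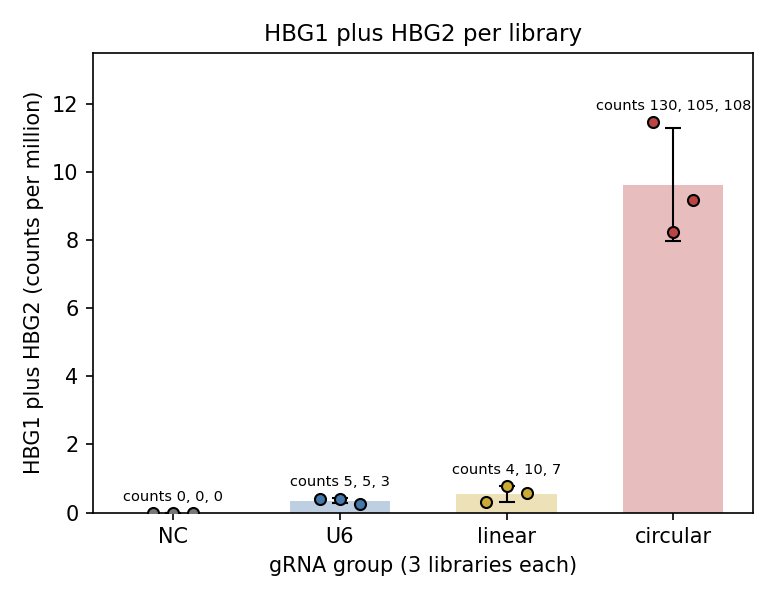
HBG1 plus HBG2 in CPM (vertical axis) for the 4 gRNA groups (horizontal axis). Points are libraries, bars are group means, error bars are the SD (n = 3), and the counts of each library are printed above. The circular libraries lie between 8.25 and 11.5 CPM, and the highest of the other libraries is at 0.775 CPM.

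With the circular gRNA the sum was higher than with either other HBG gRNA. Against U6 the log2 fold change was 4.72 (SE 0.263; edgeR quasi-likelihood test, adjusted p = 9.08e-14), with a ratio of count rates of 27.1 (95% exact interval 15.6 to 51.4). Against the linear gRNA it was 4.08 (SE 0.238; edgeR adjusted p = 3.12e-13), with a ratio of 17.2 (11.1 to 28.2). Every circular library lay above every other library. Linear and U6 were not told apart: the log2 fold change was 0.64 (SE 0.505; edgeR adjusted p = 0.907), and the ratio of 1.58 had an interval of 0.753 to 3.42. In exact two-sided permutation tests of the CPM values, p was 0.1 for each comparison with the circular group and 0.3 for linear against U6. The smallest p that 3 against 3 libraries allow is 0.1.

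Against NC, the sum was at least 116-fold higher with the circular gRNA, at least 6.71-fold higher with the linear gRNA and at least 4.24-fold higher with the U6 gRNA, taking the floor of 3 counts over the NC group. These bounds take the mean of the HBG-targeting group as exact. The counting error of its 343, 21 and 13 counts is not covered, so the true limits are lower. The edgeR adjusted p was 3.84e-15 for circular and 0.0325 for linear, and 0.427 for U6. The exact permutation p was 0.1 in each of these comparisons, the smallest possible. The linear call rested on few counts: it was lost with DESeq2 (adjusted p = 0.0635) and without linear replicate 2 (edgeR adjusted p = 0.109), circular replicate 3 (0.0597), NC replicate 1 (0.303), NC replicate 2 (0.083) or NC replicate 3 (0.0852). Over the alternatives run its adjusted p ranged from 0.000328 with limma-voom to 0.303. The U6 rise passed with limma-voom (adjusted p = 0.0115), without a low-count filter (edgeR adjusted p = 0.0393) and without linear replicate 2 (0.0311), with a range over the alternatives from 0.0115 to 0.906.

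Other genes of the globin clusters stayed at or near 0. HBB and HBE1, the adult and embryonic beta-like globin genes, had 0 counts in all 12 libraries. HBD and the pseudogene HBBP1 had 1 count each, in the circular group. BGLT3, a noncoding gene between HBG1 and HBBP1, had 4 counts in circular, 1 in U6 and 0 in linear and NC. In the alpha-globin cluster, HBA1 had 1 count in each of the HBG-targeting groups, HBA2 had 1 in circular, 2 in linear and 1 in U6, and NC had 0 of both. HBZ had 5 counts in circular, 1 in linear, 2 in U6 and 3 in NC, and HBQ1 1, 5, 6 and 1. TRIM6 was, besides HBG1, the gene near the locus with enough counts to test, and its log2 fold change in circular against NC was -0.14 (SE 0.093; edgeR adjusted p = 0.634). RELA encodes p65, part of which is in VPR; its log2 fold change in circular against NC was 0.08 (SE 0.0696; edgeR adjusted p = 0.731).

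**Figure D2:**
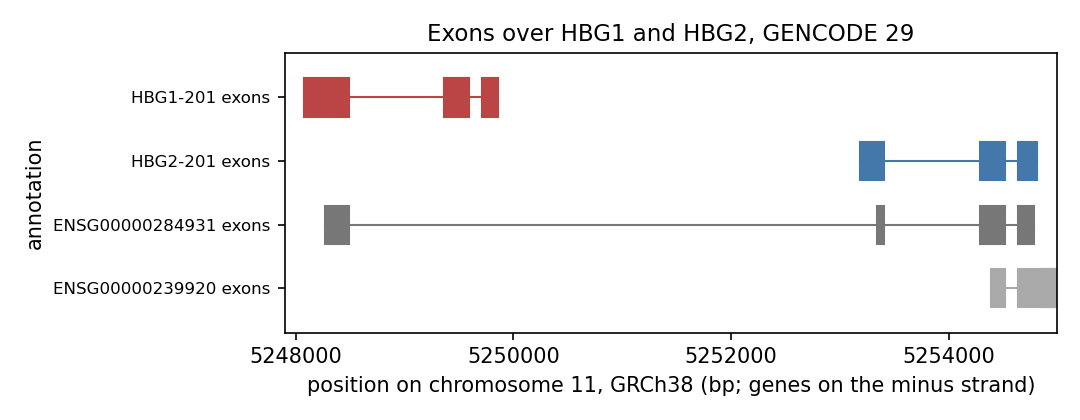
Exons of HBG1, HBG2 and the overlapping genes ENSG00000284931 and ENSG00000239920 in GENCODE 29 (vertical axis) by position in bases on chromosome 11 of GRCh38 (horizontal axis). Boxes are exons, and those of the lower genes overlap 75.1% of the HBG2 transcript and 28% of the HBG1 transcript.

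The effect on the rest of the transcriptome was asked next. With the circular gRNA, 49 of 16285 genes differed from NC (edgeR, adjusted p under 0.05): 44 rose and 5 fell. HBG1 was not the most abundant of the genes that rose. PARP14, an ADP-ribosyltransferase of the interferon response on chromosome 3 (122680618 to 122730840), had a mean of 28.7 ± 3.64 CPM (SD, n = 3) with the circular gRNA, against 0.605 with U6, 0.210 with linear and 0.109 with NC. Its 1024 counts against 4 in NC gave a ratio of 259 (95% exact interval 101 to 952; edgeR adjusted p = 7.29e-22). Per kilobase of the gene length in the files, PARP14 was at 2.79 CPM and HBG1 at 6.55 CPM in the circular group. ARHGAP36, a gene that acts in Hedgehog signalling, was at 5.51 ± 1.28 CPM and had 0 counts in NC, at least 66.6-fold higher (edgeR adjusted p = 8.02e-12). LINC01013, a long intergenic noncoding RNA, had 204 counts against 1 in NC, a ratio of 206 with an interval of 36.6 to 8190.

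The other rises under the naming rule, which asks for a mean of 1 CPM over the 12 libraries, were smaller; SERPINA9, LILRA1, PIWIL1, MBL2 and WNT8A, below that level and named after their values were seen, had 39 to 85 counts in circular against at most 1 in NC. ANKRD26P1, a transcribed pseudogene, was at 5.10 ± 0.422 CPM against 0.166, with a log2 fold change of 4.86 (SE 0.354). The log2 fold change was 2.65 for the noncoding PCAT19, 2.49 for ABCD2, a peroxisomal fatty acid transporter, 2.26 for the processed pseudogene MARK2P9, 2.20 for SHROOM2, an actin-binding protein, and 2.16 for COL9A2, a collagen IX chain. Their SEs lay between 0.193 for COL9A2 and 0.347 for MARK2P9, and the edgeR adjusted p was at most 0.000151. Reads of the pseudogenes may come from related copies, as the handling of multimapping reads is not given in the sources used here. The 5 genes that fell were BDKRB2, the bradykinin B2 receptor (log2 fold change -1.47, SE 0.31), IRS4-AS1 (-0.54), STEAP2, a metalloreductase (-0.39), PDK1, a pyruvate dehydrogenase kinase (-0.31), and ALDH1L2, a mitochondrial folate enzyme (-0.29). IRS4-AS1 is antisense to IRS4, and without stated strand use reads of the partners cannot be told apart. The edgeR adjusted p of these falls lay between 0.00164 for IRS4-AS1 and 0.0248 for PDK1. With 1 library left out, PDK1 lost the call in 5 of 12 fits (circular replicates 1, 2 and 3, NC replicates 1 and 2; edgeR adjusted p up to 0.37), ALDH1L2 in 4 (circular replicates 1 and 3, NC replicates 1 and 3; up to 0.144), BDKRB2 in 3 (circular replicates 1 and 2, NC replicate 3; up to 0.325) and STEAP2 in 3 (circular replicates 1 and 3, NC replicate 3; up to 0.201). The balance of rises and falls depended on the setting. The count of 49 was 171 without linear replicate 2 (91 rises, 80 falls), 126 without a low-count filter (82 rises, 44 falls) and 129 in a fit of these 2 groups alone (73 rises, 56 falls).

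**Figure D3:**
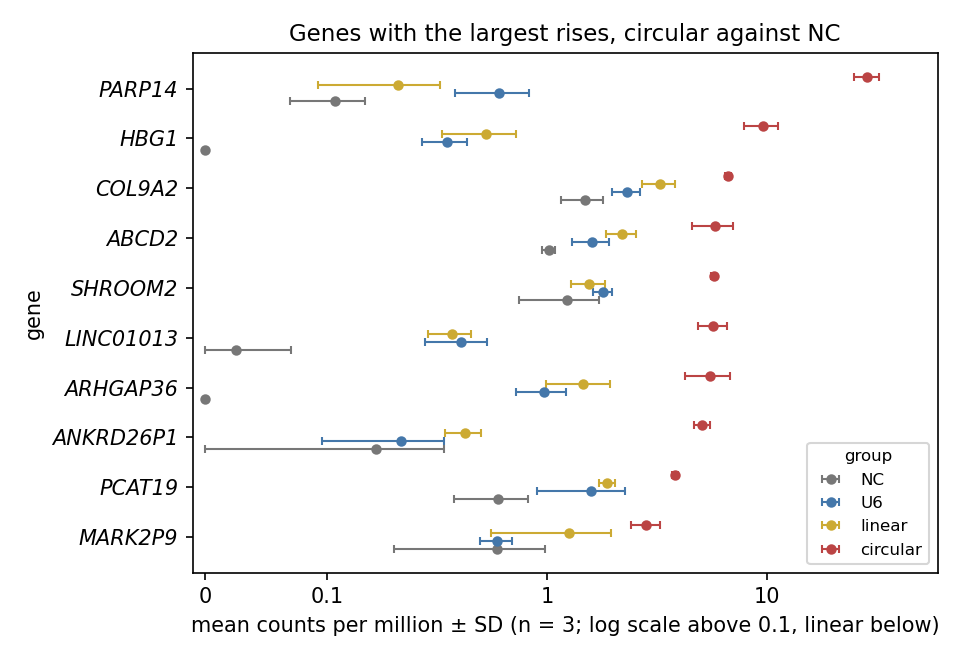
Mean CPM (horizontal axis, log scale above 0.1 and linear below) of the genes with the largest rises in circular against NC among those with a mean of at least 1 CPM (vertical axis), in each of the 4 groups; error bars are the SD (n = 3). The circular means lie to the right of the other 3 groups for each gene, with PARP14 highest at 28.7 CPM.

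With the linear gRNA, 7 genes rose and 1 fell against NC (edgeR, adjusted p under 0.05). FOSL2, an AP-1 transcription factor subunit, rose from 7.74 ± 1.08 to 16.3 ± 0.794 CPM, a log2 fold change of 1.07 (SE 0.119; edgeR adjusted p = 4.38e-06). ARHGAP36 reached 1.46 ± 0.47 CPM, at least 17.6-fold higher than NC (edgeR adjusted p = 3.67e-05). PIWIL1, which encodes a PIWI protein of the germline and is named after its values were seen to complete the count, had 46 counts against 0, at least 14.7-fold higher (edgeR adjusted p = 3.17e-05). COL9A2 and KCNA2, a voltage-gated potassium channel, rose by log2 fold changes of 1.135 (SE 0.222) and 0.71 (SE 0.139), both with an edgeR adjusted p of 0.0329. The other risen genes were HBG1 and ENSG00000286795, which has no symbol and was named after its values were seen, and IRS4-AS1 fell by 0.49 on the log2 scale (SE 0.0954; edgeR adjusted p = 0.0329). Linear replicate 2 stood furthest from its replicates, with a chi-square per degree of freedom of 4.66 against replicate 1 and 5.37 against replicate 3, beside 1.79 between replicates 1 and 3. Without linear replicate 2 the count of 8 was 6, and without linear replicate 3, with replicate 2 kept, it was 744 (428 rises, 316 falls). It was 4 without NC replicate 2 and 5 without U6 replicate 3, circular replicate 3 or NC replicate 1. No low-count filter gave 230 (141 rises, 89 falls), the replicate block 23 (15 rises, 8 falls) and offsets for GC content and gene length 30 (17 rises, 13 falls). COL9A2 and KCNA2 each lost the call in 7 of 12 fits with 1 library left out (U6 replicate 3, linear replicates 1 and 2, circular replicate 3, and each NC replicate; edgeR adjusted p up to 0.424 and 0.41). HBG1 alone lost it in 7 (U6 replicates 1 and 3, linear replicate 2, circular replicate 3, and each NC replicate; up to 0.33). IRS4-AS1 lost it in 4 (linear replicates 1 and 2, NC replicates 1 and 2; up to 0.424).

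With the U6 gRNA, 3 genes rose against NC and 0 fell (edgeR, adjusted p under 0.05); 1516 genes had an unadjusted p under 0.05. DESeq2 and limma-voom also found 0 falls. FOSL2 rose to 14.8 ± 1.02 CPM (log2 fold change 0.93, SE 0.122; edgeR adjusted p = 0.000162). PIWIL1 had 33 counts against 0, at least 10.8-fold higher (edgeR adjusted p = 0.000698), and ARHGAP36 36 counts against 0, at least 11.8-fold higher (edgeR adjusted p = 0.00174). BDKRB2 and ADGRV1, an adhesion G protein-coupled receptor, had the next smallest p-values, with log2 fold changes of -1.61 (edgeR adjusted p = 0.0579) and -0.40 (edgeR adjusted p = 0.423). Some other settings gave mostly falls. Without linear replicate 2, 23 genes rose and 84 fell; in a fit of these 2 groups alone 20 rose and 102 fell, and without a low-count filter 12 rose and 30 fell. The replicate block gave 3 rises and 2 falls, the GC and length offsets 4 rises and 1 fall, and limma-voom 6 rises.

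The risen genes of the 3 HBG gRNAs overlapped. All 7 genes that rose with the linear gRNA and all 3 that rose with U6 were among the 44 that rose with the circular gRNA. Of the 44 genes, 42 lay above NC in linear and 42 in U6. The comparisons share the NC libraries, which raises such counts without any effect, so the counts alone do not show a shared effect. Across genes, which are not independent replicates, Pearson's r between the fold changes was 0.689 for circular with linear, 0.645 for circular with U6 and 0.675 for linear with U6. Simulated unchanged groups that shared their simulated controls gave 0.504, 0.500 and 0.505. The covariances were 0.0462, 0.0417 and 0.0359, and exceeded the simulated ones by 0.0307, 0.0263 and 0.0205. The simulation drew every group around the mean of the 12 libraries, gene by gene, so it held no genes absent from NC alone and no GC or length trends. Genes with 0 counts in NC, such as ARHGAP36 (log2 fold changes of 9.07 in circular and 7.16 in linear), add to the observed values. The excess therefore does not measure a change shared by most genes. With 3 NC libraries the controls could not be split into parts of 2, so the overlap was not measured against separate controls.

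Circular and U6 gRNA differed in 36 genes, all higher with the circular form (edgeR, adjusted p under 0.05), and 642 genes had an unadjusted p under 0.05. DESeq2 called 27 and limma-voom 34, also with 0 lower. Some settings gave genes lower with the circular form: 3 of 48 with the GC and length offsets, and 1 each without a low-count filter, linear replicate 2, circular replicate 2 or circular replicate 3. Under the naming rule the largest log2 fold changes were 5.56 for PARP14 (SE 0.183), 4.72 for HBG1, 4.48 for ANKRD26P1 (SE 0.334) and 3.77 for LINC01013 (SE 0.273). AZGP1 and MBL2, named after their values were seen, had 42 and 39 counts in circular against 0 and 2 in U6 and fell short of that rule's 1 CPM. ARHGAP36 was higher by 2.47, MARK2P9 by 2.22, ABCD2 by 1.85, SHROOM2 by 1.68 and DCLK1, a microtubule-associated kinase, by 1.58. RTL9, a retrotransposon-derived gene, was higher by 1.71 (SE 0.265), where U6 had 0.919 ± 0.166 CPM, circular 3.04 ± 0.862 and NC 2.12 ± 0.273. The edgeR adjusted p was at most 0.000263 among the genes under the rule and 0.001 for MBL2. CCN2, a matricellular growth factor among the immediate early genes, was higher by 0.82 (SE 0.157; edgeR adjusted p = 0.0311). It lost the call in 8 of 12 fits with 1 library left out (each U6 replicate, linear replicate 3, circular replicates 1 and 3, NC replicates 1 and 2; edgeR adjusted p up to 0.284). The count of 36 was 24 without circular replicate 1.

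Circular and linear gRNA differed in 32 genes, again all higher with the circular form (edgeR, adjusted p under 0.05). The log2 fold change was 7.01 for PARP14 (SE 0.219), 4.15 for HBG1 (SE 0.239), 3.91 for LINC01013 and 3.55 for ANKRD26P1. ARHGAP36 was higher by 1.90, SHROOM2 by 1.87, the phosphodiesterase PDE4B by 1.41, ABCD2 by 1.39, the metalloprotease ADAMTS8 by 1.35 and COL24A1, a collagen chain, by 1.33. PDE4B had the largest edgeR adjusted p of these, 0.0131, and lost the call without linear replicate 1, linear replicate 2, circular replicate 1 or circular replicate 3 (edgeR adjusted p up to 0.114). Of the 44 genes that rose against NC, 28 were also called higher in circular against both other HBG gRNA groups (edgeR, adjusted p under 0.05). By mean CPM, 44 of 44 lay higher in circular than in both. The count of 32 was 21 with DESeq2 and 21 without circular replicate 3. Without linear replicate 2, 35 genes were higher and 10 lower with the circular form, without a low-count filter 52 higher and 3 lower, and with the GC and length offsets 34 higher and 1 lower.

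Linear and U6 gRNA differed in 0 genes with edgeR, and 985 genes had an unadjusted p under 0.05; DESeq2 and limma-voom also called 0. Without linear replicate 2 the edgeR count was 27, and without a low-count filter it was 10. The smallest p-values belonged to SMG5, MTATP6P1, ACTR6, RTL9 and PMAIP1, all with an edgeR adjusted p of 0.524. RTL9 had the largest difference of these, 2.15 ± 0.104 CPM in linear against 0.919 ± 0.166 in U6, a log2 fold change of 1.21 (SE 0.284).

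For the mean of the 3 HBG-targeting groups against NC, 17 genes rose and 7 fell (edgeR, adjusted p under 0.05). The largest rises under the naming rule were ARHGAP36, HBG1, LINC01013, ABCD2 (log2 fold change 1.41, SE 0.231) and COL9A2 (1.31, SE 0.186). The largest falls were BDKRB2 (-1.51, SE 0.242), RASGRP3, a Ras guanine nucleotide exchange factor (-1.09, SE 0.225), IRS4-AS1 (-0.46), STEAP2 (-0.31) and PDK1 (-0.29). BDKRB2 was at 2.15 ± 0.655 CPM in NC and at 0.785 with circular, 0.793 with linear and 0.702 with U6. The count of 24 was 231 without linear replicate 3 (114 rises, 117 falls), 77 without linear replicate 2 (39 rises, 38 falls), 15 without NC replicate 1 (14 rises, 1 fall), 37 with the replicate block (20 rises, 17 falls) and 277 without a low-count filter (118 rises, 159 falls). RASGRP3 lost the call in 5 of 12 fits with 1 library left out (U6 replicates 1 and 3, circular replicate 3, NC replicates 1 and 2; edgeR adjusted p up to 0.571). STEAP2 lost it without NC replicate 1 or 3, PDK1 without NC replicate 1 or 2, IRS4-AS1 without NC replicate 1 and BDKRB2 without NC replicate 3 (edgeR adjusted p up to 0.383). A test of any difference among the 4 groups called 49 genes. The count was 212 without linear replicate 2, 115 without linear replicate 3 and 237 without a low-count filter.

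Gene lists fixed before the data were examined moved little. In circular against NC, the beta-globin list had 1 tested member, HBG1. Of 34 tested genes of the interferon response, PARP14 alone rose, also when adjusted over the list alone; the median log2 fold change of the list was 0.03, and camera did not call it (adjusted p = 0.304; adjusted p = 0.633 with an estimated correlation). Without PARP14, an alternative added after the data were seen, the highest of the other 33 was DHX58 at 0.40 (SE 0.232; edgeR adjusted p = 0.584). Of 24 immediate early genes CCN2 alone rose, by 1.00 (SE 0.161; edgeR adjusted p = 0.00401; 0.0974 without NC replicate 1), and of 25 hypoxia and glycolysis genes PDK1 alone fell, with 2 falls when adjusted over the list alone. No member of the remaining lists passed over all genes tested. Adjusted over the list alone, 1 gene rose among the NF-kB targets, 2 among the integrated stress response and unfolded protein response and 1 among the histone genes. Camera with a preset correlation of 0.01 called 3 of 21 lists higher in circular against NC. These were the cytosolic ribosomal proteins (71 of 74 above 0, median 0.08; camera adjusted p = 2.4e-17, adjusted p = 0.534 with an estimated correlation), the alpha-globin cluster (6 tested, median 0.17; camera adjusted p = 0.0374, adjusted p = 0.337 with an estimated correlation) and the p53 targets (22 tested, median 0.07; camera adjusted p = 0.0374, adjusted p = 0.337 with an estimated correlation). The tested members of the alpha-globin list were flanking genes such as LUC7L and POLR3K, not globins. The other 18 lists, among them erythroid genes, globin switching regulators, heat shock proteins, cholesterol synthesis, S phase genes, G2 and M phase genes, replication-dependent histone genes, the tRNA splicing ligase and endonuclease, RNA polymerase III subunits and U6 promoter factors, and hematopoietic, fibroblast and mesenchymal, epithelial, and neuronal and neural crest markers, had camera adjusted p between 0.0747 and 0.851. The median and mean of a list differed in sign for the globin switching regulators, heat shock proteins, immediate early genes, hypoxia and glycolysis genes, RNA polymerase III subunits and fibroblast markers. With the GC and length offsets the alpha-globin call was lost (camera adjusted p = 0.154). The count of 3 called lists was 1 without circular replicate 2, circular replicate 3, NC replicate 2 or NC replicate 3.

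In linear against NC, camera called the alpha-globin cluster (adjusted p = 0.0253; adjusted p = 0.532 with an estimated correlation) and the ribosomal proteins (adjusted p = 0.0167; adjusted p = 0.828 with an estimated correlation) higher, and the interferon response lower (median -0.09; adjusted p = 0.00455; adjusted p = 0.532 with an estimated correlation). In the interferon list edgeR called 0 genes over all genes tested, and 4 fell when adjusted over the list alone; 3 of the alpha-globin list rose and 1 ribosomal protein gene rose in that way. Without linear replicate 2, 5 lists were called. Ribosomal protein genes lay higher in linear replicate 2 than in the other linear libraries, by a median log2 value of 0.14, as did immediate early genes (0.26) and the integrated stress response and unfolded protein response (0.08), 2 lists called lower in linear against U6. With the GC and length offsets the ribosomal (camera adjusted p = 0.334) and alpha-globin (0.146) calls were lost, and 5 lists were called lower in addition to the interferon response: heat shock proteins (0.0115), immediate early genes (6.29e-05), hypoxia and glycolysis (0.0063), cholesterol synthesis (0.0283) and neuronal markers (0.0439). In U6 against NC the ribosomal proteins (adjusted p = 1.3e-20; adjusted p = 0.712 with an estimated correlation) and the integrated stress response and unfolded protein response (median 0.05; adjusted p = 0.000633; adjusted p = 0.604 with an estimated correlation) were called higher. Adjusted over the list alone, 3 genes of the latter rose. Without U6 replicate 1, 4 lists were called.

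Between the HBG gRNAs, camera called the interferon response (adjusted p = 0.025; adjusted p = 0.663 with an estimated correlation), p53 targets (adjusted p = 0.0316; adjusted p = 0.663 with an estimated correlation) and histone genes (adjusted p = 0.0263; adjusted p = 0.484 with an estimated correlation) higher in circular than in U6, and immediate early genes lower (adjusted p = 0.025; adjusted p = 0.946 with an estimated correlation). The interferon call was lost without PARP14 (camera adjusted p = 0.215; adjusted p = 0.946 with an estimated correlation). In circular against linear, the interferon response (adjusted p = 1.26e-09; adjusted p = 0.0759 with an estimated correlation), p53 targets (adjusted p = 0.00022; adjusted p = 0.223 with an estimated correlation), heat shock proteins (adjusted p = 0.00022; adjusted p = 0.314 with an estimated correlation) and ribosomal proteins (adjusted p = 9.5e-09; adjusted p = 0.721 with an estimated correlation) were called higher; adjusted over the list alone, 10 interferon genes and 4 heat shock genes rose. Without PARP14 the interferon call remained (camera adjusted p = 3.06e-07; adjusted p = 0.223 with an estimated correlation). In linear against U6, 5 lists were called lower: the interferon response (adjusted p = 0.000153; adjusted p = 0.317 with an estimated correlation), the integrated stress response and unfolded protein response (adjusted p = 0.000199; adjusted p = 0.317 with an estimated correlation), heat shock proteins (adjusted p = 0.0252; adjusted p = 0.501 with an estimated correlation), immediate early genes (adjusted p = 1.85e-05; adjusted p = 0.501 with an estimated correlation) and ribosomal proteins (adjusted p = 1.81e-10; adjusted p = 0.501 with an estimated correlation). The count in circular against U6 was 1 without U6 replicate 1 or circular replicate 3 and 2 without U6 replicate 2 or circular replicate 2. It was 8 in circular against linear without linear replicate 2, and 3 in linear against U6 without linear replicate 1. The heat shock call in linear against U6 was lost with the GC and length offsets (camera adjusted p = 0.0574). The offsets added immediate early genes (camera adjusted p = 0.00969) and hypoxia and glycolysis (0.0356) as higher in circular against linear, and globin switching regulators (0.0176) as lower in linear against U6. With an estimated correlation, and with fry, 0 lists passed in each of the 6 comparisons. All 37 mitochondrially encoded genes, RN7SK and RMRP had 0 counts in every library, so the mitochondrial list was not tested. Of the non-polyadenylated RNAs 2 were tested, and RN7SL1 had a log2 fold change of 0.60 in circular against NC (SE 0.283; edgeR adjusted p = 0.542).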

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

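The GC and length offsets were chosen only after the data were seen; the other settings of this part were fixed before. The rise of HBG1 plus HBG2 in circular against NC, U6 and linear passed in all settings run, with log2 fold changes against U6 of 4.56 to 4.83 and against linear of 3.80 to 4.404 with 1 library left out. Against NC these ranged from 9.74 to 9.97 for circular, 5.46 to 6.07 for linear (the call was lost in 5 of 12) and 5.04 to 5.32 for U6 (called in 1 of 12); linear against U6 ranged from 0.32 to 0.92. Values against NC, where the counts are 0, depend on the tool and are no measured folds: limma-voom gave 7.85 for circular and 3.76 for linear. The linear call ended with DESeq2 (log2 fold change 5.18, adjusted p 0.0635), and the U6 call passed with limma-voom (3.23, adjusted p 0.0115) and without a low-count filter (5.15, edgeR adjusted p 0.0393); the cause was not tested. HBG2 alone, and the sum in fits of linear and NC, U6 and NC, or linear and U6 alone, were below the filter and could not be fitted, and a fold limit gives no value for the test among 4 groups.

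Counts of called genes in circular against NC, linear against NC, U6 against NC, circular against linear, linear against U6, the mean contrast and the 4-group test became 126, 230, 42, 55, 10, 277 and 237 without a low-count filter, which tested 38197 genes; the rises and falls there were 82 and 44, 141 and 89, 12 and 30, and 118 and 159 in circular, linear, U6 and the mean against NC. DESeq2 gave 21 for circular against linear, and limma-voom 6 for U6 against NC. A fit of the 2 groups alone gave 129 (73 rises, 56 falls), 5 and 122 (20 rises, 102 falls) for circular, linear and U6 against NC; it estimates the spread from fewer libraries. The GC and length offsets gave 30 (17 rises, 13 falls) for linear against NC and 5 for U6 against NC. They kept 49 of 49, 8 of 8 and 3 of 3 calls against NC, 35 of 36 in circular against U6 and 32 of 32 in circular against linear, and gave 6 called lists in linear against NC, all lower and 5 of them not called without offsets. The alpha-globin list lost its call in circular and linear against NC, the ribosomal proteins in linear against NC and the heat shock proteins in linear against U6. The causes of the other moves were not tested.

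With 1 library left out, the counts ranged from 40 to 171 (circular against NC), 4 to 744 (linear against NC), 3 to 107 (U6 against NC), 24 to 43 (circular against U6), 21 to 45 (circular against linear), 0 to 27 (linear against U6), 15 to 231 (mean contrast) and 38 to 212 (4 groups). The highest counts came without linear replicate 2, except for linear against NC and the mean contrast, where they came without linear replicate 3. Where a group was left with 2 libraries the fit assumed that they vary like the others. Called lists ranged from 1 to 4, 2 to 5, 2 to 4, 1 to 5, 3 to 8 and 3 to 6 in the 6 comparisons, and were 0 in each with an estimated correlation and with fry. The correlations between fold changes against NC ranged from 0.591 to 0.729 (circular with linear), 0.550 to 0.691 (circular with U6) and 0.562 to 0.734 (linear with U6).

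The labels give the groups the same replicate numbers. Correlations of deviations between same-numbered libraries lay between -0.137 and 0.128, and between libraries of other numbers from -0.0777 to 0.106. As 6 of 12 libraries correlated best with their own number, the numbers were not taken to pair the samples. Linear replicate 2 had the highest values, with circular replicate 2 (0.128) and NC replicate 2 (0.123), and the lowest, with U6 replicate 2 (-0.137). A batch shared by some of these libraries was not tested. The replicate block gave 23 genes in linear against NC, 5 in U6 against NC, 1 in linear against U6 and 37 in the mean contrast.

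Of 56 called results of named genes, 6 lost the call with DESeq2, 3 with limma-voom, 1 with the block and 2 with the offsets; 3 of 43 lost it in fits of the 2 groups alone and 64 of 672 with 1 library left out, and 0 reversed. Reversals occurred in uncalled values with 1 library left out: LUC7L, circular against NC (0.003144 without circular replicate 3, 0.01005 without NC replicate 2, lowest -0.05182), LUC7L, linear against NC (0.0002653 without linear replicate 1, lowest -0.1048), RELA, circular against NC (-0.004717 without NC replicate 1, highest 0.1315) and NPRL3, U6 against NC (-0.009928 without NC replicate 1, highest 0.1566). The cause of these was not tested. Depth limits the values of genes near 0 counts in NC, where 3 counts over the group stand at 0.0828 CPM.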

Other observations

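All tests below were prompted by results that had already been seen. For gene length, GC content and YAP targets, the prediction was written before the outcome of the test itself was seen. Among the genes that rose with the circular gRNA against NC, but fell outside the naming rule and were picked after their values were seen, were several that NC lacked. Besides HBG1 and ARHGAP36, 4 of the 6 risen genes with 0 counts in NC were SERPINA9, a serpin of germinal centre B cells (85 counts, at least 28.8-fold higher), LILRA1, a leukocyte receptor (70 counts, at least 23.8-fold), PIWIL1 (66 counts, at least 22.4-fold) and MBL2, a lectin of the liver (39 counts, at least 13.3-fold). WNT8A, a Wnt ligand, had 74 counts against 1, a ratio of 74.8 with an exact interval of 13 to 3000. FN1, which encodes fibronectin, went from 33.2 to 50.7 CPM (log2 fold change 0.61; edgeR adjusted p = 3.4e-07), and THBS1 from 1.29 to 3.50 CPM (1.42; edgeR adjusted p = 0.000895).

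Genes other than HBG1 were higher with the circular gRNA. RLE and upper-quartile factors each kept 49 of 49 calls in circular against NC, so the calls did not hang on the choice among these factors and TMM. Whether an error that all these factors share added to these rises was not decided. The smallest log2 rise among them was 0.26 beside a span of 0.040 between the scaling factors. These genes were picked by their adjusted p, which keeps small rises out, so the smallest rise could hardly have come near that span. For circular against NC, a rise of the interferon list along with PARP14 is argued against: the highest of the other 33 members was at 0.40, and edgeR called 0 of them. In circular against linear, camera called these 33 higher (adjusted p = 3.06e-07; adjusted p = 0.223 with an estimated correlation). The highest there was RSAD2 at 0.76, beside 7.01 for PARP14, and edgeR called 0. Mean levels over the 12 libraries differed widely, from 581 CPM for IFIT2 to 1.94 for RSAD2. Whether members already high had room to rise was not tested. A shared activity of the HBG gRNAs was tested on separate libraries. The 35 genes higher in circular than in U6, HBG1 left out, had a median log2 fold change of 0.83 in linear against NC, with 32 above 0. The 31 genes higher in circular than in linear had a median of 0.45 in U6 against NC, with 27 above 0. In both, 0 of 10000 lists matched on level had as high a median. The level was the mean of all 12 libraries, circular included. Some chosen genes had far fewer counts in the groups compared, such as PARP14 (28.7 CPM in circular, 0.210 in linear, 0.109 in NC). The matched lists may thus vary too little. Activity at other genes that the gRNAs share would give such medians, but so would a difference between the NC gRNA and all HBG gRNAs. The gRNA sequences and their matches in the genome were not used here.

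HBG2 stayed near 0 counts in circular libraries while HBG1 had 342. In GENCODE 29, exons of other genes, such as ENSG00000284931, cover 75.1% of the bases of the HBG2 transcript and 28% of those of HBG1. Windows free of such exons and of copies shared with HBG1 would give HBG2 183 counts at the rate of HBG1 for 50-base windows, 102 for 100-base windows, 10.4 for 150-base windows and 0 for 200-base windows. Whether HBG2 was silent or its reads were left out cannot be told apart, because read length and the counting rules are not given in the sources used here. No biological difference between the genes was tested.

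Linear replicate 2 stood apart from the other libraries. Across 9905 genes, which are not independent replicates, its deviation from the other linear libraries had a Spearman rho of -0.469 with gene length, the largest in size of 12, and, across the 9898 of them with a GC value, of 0.619 with GC content. By the criterion set beforehand GC alone stays open, because linear replicate 3, whose reference includes replicate 2, had -0.636. Offsets for both trends removed 49.7% of the variance of its deviation, as the SD fell from 0.165 to 0.117. The share computed from the median SDs of the other libraries before and after was 9.21%, which is no median of their own shares. Single libraries differed in this: the SD fell from 0.132 to 0.101 in linear replicate 3 and from 0.119 to 0.102 in NC replicate 1. In U6 replicate 3 it went only from 0.0941 to 0.0926. A bound for the 49.7% share was chosen after both SDs of linear replicate 2 were known. After the offsets linear replicate 2 stayed above the SDs of 0.092 to 0.104 of the other libraries, so the trends may be part of the cause and the rest is open. Without it the biological coefficient of variation was 3.23%, against 3.94% to 4.37% without any other library, which is consistent with a spread raised in all comparisons; no biological explanation was tested.

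Called genes within 250 kb of one another formed 3 pairs (HLA-DRA with HLA-DQB1, CCN2 with LINC01013, FMR1-AS1 with FMR1), against a mean of 0.954 in random sets, of which 760 of 10000 had as many; the window was set knowing that CCN2 and LINC01013 are 180.5 kb apart. A hypothesis that CCN2 and THBS1 rose as targets of the YAP and TEAD transcription factors was tested on a list of other targets that held neither gene. Over its 20 tested genes the median was -0.018 in circular against NC (camera p = 0.80 with an estimated correlation), so those targets did not rise with them; CCN2 and THBS1 themselves were not part of the test.

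Other splits of the same libraries were refitted. For pairs of groups 3 against 3 libraries make 10 splits, too few for a share under 0.05. The real split was among the splits with as many genes 1 time of 10 in circular against NC (49 genes, highest other 0), 1 in linear against NC (8, highest other 1), 1 in U6 against NC (3, highest other 0), 1 in circular against U6 (36, highest other 0), 2 in circular against linear (32, highest other 119) and 10 in linear against U6 (0, highest other 323). For the mean contrast 7 of 100 splits gave at least 24 genes, with a highest of 1171, and for the test among 4 groups 11 of 100 gave at least 49, with a highest of 940, so chance cannot be excluded for these counts. With the GC and length offsets 8 of 100 splits gave at least 29 genes (highest 255) and 10 of 100 at least 72 (highest 312), and chance cannot be excluded either. The largest counts, several times the real ones, point to a structure of the samples; the highest split of the mean contrast put U6 replicate 3, linear replicate 2 and circular replicate 2 in place of NC.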
